A study of Mus musculus with 41 samples.

How the data were processed

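Liver RNA of female B6C3F1 mice, a cross of C57BL/6 and C3H mice, was measured on 41 Agilent 1-colour mouse expression arrays, each holding 1 sample labelled with the dye Cy3. Per the labels, mice were irradiated from 8 weeks of age with gamma rays of 137Cs at 20 mGy per day, for 22 hours a day over 400 days, to a total of 8 Gy, and were then kept for 100, 200 or 300 days without irradiation. The day on which each mouse was sampled is not given in the sources used here. The labels put 11 samples in the control group, 10 in the group of irradiated mice without hepatocellular adenoma (HCA), 10 in the group of non-adenoma liver of irradiated mice with HCA and 10 in the group of adenomas. They do not say that samples of a group came from separate mice, so the p-values measure the spread between these samples. This spread was estimated once per gene over the 4 groups.

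The deposited scanner files hold the intensity of each spot on a linear scale, as gProcessedSignal, with the background already subtracted by Agilent Feature Extraction, per the file headers. The headers name version 10.7.1.1 of that software and the submitters' processing notes name version 13.0, and the difference was not resolved. The authors also deposited a table of processed values, which are on a log2 scale by comparison with the scanner intensities. Differences between arrays in that table followed those of log2 gProcessedSignal (lowest correlation 1, slope 1) up to a constant for each array, which against control 1 lay between -1.74 and 0.39. Against the values less the 75th percentile of each array, used here, the constants lay between -0.01 and 0.06, so the table had been scaled between arrays nearly as that percentile does. The median of every probe over the 41 arrays was 0 (100% of 41022 probes), so the probes had been centred. In the order of the replicate numbers, column medians of the table were -0.06, 0.14, 0.16, 0.01, -0.07, 0.15, 0.16, 0.06, 0.09, -0.03 and 0.04 in controls. In irradiated liver without HCA they were 0.18, -0.02, -0.15, 0.06, 0.16, 0.05, -0.38, 0.06, 0.09 and -0.02. In non-adenoma liver they were -0.16, -0.09, 0, -0.07, 0, 0.05, -0.02, -0.03, 0.002 and 0.28. In adenomas they were -0.13, -0.26, -0.26, -0.14, 0, -0.30, -0.24, -0.23, -0.17 and -0.02. The direction is that of the scanner values, and the exact rule of the scaling stays unknown. This table served only as an alternative.

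The main values were log2 gProcessedSignal minus the 75th percentile of each array, computed here. Spots of 1 probe were averaged, control spots were left out, and 152 probes were left out for spots marked as outliers. Of 41174 probes, 28265 carried a RefSeq accession, and 27479 of them were named through a RefSeq gene table of the mouse assembly GRCm38.p6, which gave 18749 gene symbols. The other 13695 probes stayed unnamed and were not tested by gene. The arrays came in 2 design versions, in which 506 spots differed in their accession. A probe was kept where it was well above background on at least 8 arrays of at least 1 group, which left 22437 probes, and each gene was represented by the probe with the highest mean over the 41 arrays, which left 12716 genes. Of these genes, 4007 had several probes past the filter. Among 2193 such genes that changed between adenoma and non-adenoma liver, every other probe gave the same call in 1327 and a probe changed in the opposite direction in 96. Against irradiated liver without HCA the numbers were 1951, 1159 and 59. None of the genes named below for a large change, a low p in a tested list or as fixed genes was among those with an opposite probe. Other list members named below, such as Ctrb1 and Cel, were not checked for this.

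Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend and robust settings) in 1 fit of the 41 arrays with group and slide run as terms, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 41 arrays lay on 11 slides of 3 runs, and were scanned on 5 dates. Most slides held samples of 1 group. All 38 gene lists were fixed before the data were examined, as were the fit, the filter and the rule for named genes, and 35 lists had at least 5 tested genes. Lists were tested with camera of limma at a preset correlation between genes of 0.01, with adjustment over the 35 lists. Camera compares the genes of a list with the other genes. The same lists were tested with an estimated correlation and with fry, whose directional p asks whether the genes of a list move on balance one way and whose mixed p asks whether they change in either direction. Neither compares a list with other genes. Counts of members that passed are given from the fit over all genes and, beside them, adjusted over the list alone.

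By the rule for named genes, the text may name the 10 genes with the largest positive and the 10 with the largest negative log2 fold change past the threshold in each comparison, up to 4 members with the lowest p in each list, and any list member whose value is given whether or not it passed. Cdkn1a, Afp, Glul, Saa1, Cyp7b1 and Cyp2b9 are given in every comparison. Names that are only an accession, a clone or a number were passed over, and the results of 2 genes within the rule are not reported here. Counts of arrays well above background are those of the gene's probe with the most such arrays, which may not be the tested probe. For a gene not well above background on any array of a group, the fold is given as a lower bound. It was taken against the higher of the probe's own signal and the lowest signal among probes well above background on each array.

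The procedure was tested on simulated data for 12716 genes with changes of known size. For irradiated liver without HCA against control, 41.8% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 98.5% of those changed by 2 were recovered, with 6 false calls. For non-adenoma liver against irradiated liver without HCA the shares were 38.8%, 77.6% and 98.5%, with 4 false calls. For adenoma against non-adenoma liver they were 31.3%, 83.6% and 97.0%, with 7 false calls, and for adenoma against irradiated liver without HCA 34.3%, 77.6% and 97.0%, with 12 false calls. These shares and false calls hold for normally distributed noise, with 1 spread per gene in all groups and no correlation between genes. They do not cover a spread that differs between groups, genes that vary together or the arrays that stood apart.

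Alternatives were normexp background correction with an offset of 50, quantile and median scaling, the deposited table, no filter and a filter over all arrays, every probe by itself, no run term, slide as a random block, scan date as a term, fits within runs, only the 2 groups compared, a block of replicate numbers, array weights, other thresholds and leaving out each array. The normexp alternative was planned on mean signals. The files used here hold median signals, and these were taken in their place. Fits within scan dates, list tests within runs and with scan date as a term, values of named genes in fits by run, by scan date and of only the 2 groups, and fits without arrays that stood apart were added after seeing the data. An array of the 3 groups without adenoma tissue was counted as standing apart where its median correlation with the others was under 0.96, a limit set after the correlations were seen. Control 5, irradiated 5, irradiated 7 and irradiated 8 lay under it at 0.913, 0.923, 0.866 and 0.952, and irradiated 3 lay just above it at 0.961. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.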

Results

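Transcript levels were measured on 41 arrays: 11 of control liver, 10 of liver of irradiated mice without HCA, 10 of non-adenoma liver of irradiated mice with HCA and 10 of adenomas. HCA is a benign tumour of hepatocytes. The 75th percentile of the signal lay between 162 and 361 in controls, 132 and 598 in irradiated liver without HCA, 185 and 376 in non-adenoma liver and 225 and 452 in adenomas. Between 49.0% and 63.7% of probes were well above background on an array, and the number of arrays limits the precision. Values are log2 fold changes ± SE from limma, with n = 10 per group and n = 11 for controls, and adjusted p-values are from Benjamini-Hochberg adjustment. Each SE rests on 1 estimate of the spread of a gene, shared by the 4 groups. The SD of Glul, however, was 3.58 in adenomas and 0.3 in non-adenoma liver. It was 1.07 in irradiated liver without HCA and 0.35 in controls. For such genes an SE may be too small where adenomas are compared and too large between the other groups.

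The comparison of adenoma with non-adenoma liver asked how the tumours differed from liver without adenoma tissue of irradiated mice with HCA. The labels do not say which of these samples came from the same mouse, and the fit was not paired. Afp, the fetal serum protein alpha-fetoprotein, rose by 7.22 ± 0.80 on the log2 scale (adjusted p = 3.26e-08, higher in 10 of 10 adenomas than the non-adenoma mean). Akr1c18, an aldo-keto reductase that metabolises progesterone, rose by 6.94 ± 0.79 (adjusted p = 4.29e-08, 9 of 10), and the tetraspanin Tspan8 by 6.07 ± 0.77 (adjusted p = 2.11e-07, 10 of 10). Cyp2f2, a cytochrome P450 of periportal hepatocytes, fell by 4.67 ± 0.76 (adjusted p = 6.03e-06, lower in 10 of 10), and Cyp8b1, an enzyme of cholic acid synthesis, fell by 4.32 ± 0.65 (adjusted p = 1.95e-06, 9 of 10).

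In limma, 6957 of 12716 genes (54.7%) passed, 2721 higher and 4236 lower in adenomas, and the median over all genes was -0.12. Further genes with the largest increases were Tff3, a peptide of mucous epithelia (6.99 ± 1.40), Gpc3, a cell surface proteoglycan (5.65 ± 1.04), Bex2 (4.87 ± 0.82), the pancreatic elastase Cela1 (4.81 ± 0.55), the intestinal keratin Krt20 (4.65 ± 0.90) and the fatty acid elongase Elovl7 (4.54 ± 0.58). In non-adenoma liver Gpc3 and Elovl7 were well above background on 8 of 10 arrays, Akr1c18 on 8, Krt20 on 5, Cela1 on 3 and Bex2 on 1. Prnd, a relative of the prion protein, was not well above background on any non-adenoma array and was at least 6.61-fold higher in adenomas (adjusted p = 7.69e-09, 9 of 10). Dct, an enzyme of melanin synthesis, fell by 8.00 ± 1.12 (adjusted p = 6.43e-07) and was well above background on 7 of 10 adenomas. A1bg, a plasma glycoprotein, fell by 7.36 ± 1.44 (adjusted p = 6.6e-05) and was well above background on 5. Sult2a7, a sulfotransferase, fell by 5.80 ± 0.95 and Lrtm1 by 5.26 ± 0.79. In adenomas Cyp2f2 and Sult2a7 were well above background on 9 of 10 arrays, Lrtm1 on 8 and Cyp8b1 on 4. The iron hormone genes Hamp and Hamp2 had values of -4.26 ± 1.08 and -5.42 ± 1.14 and passed as lower, and the urinary protein gene Mup6 fell by 5.21 ± 0.97. Probes of these 3 genes cannot be taken as specific, because the genes belong to families of near-identical copies.

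**Figure D1:**
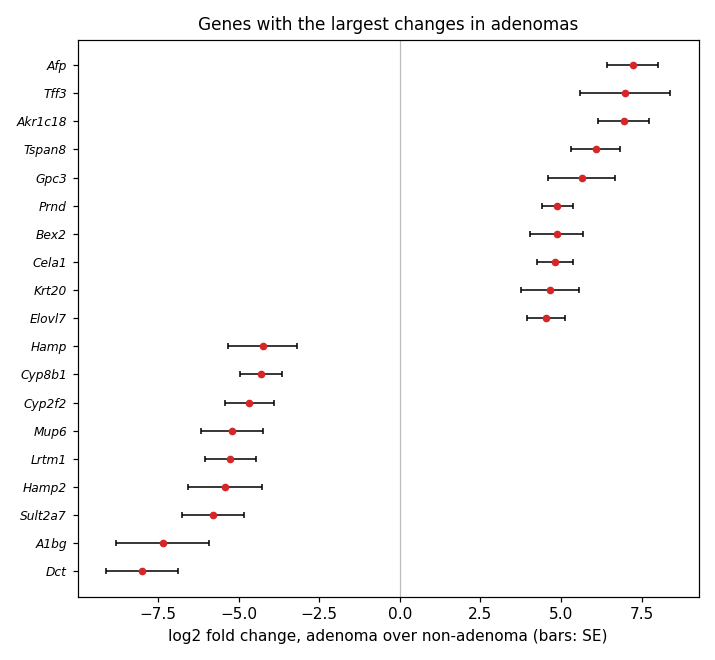
Log2 fold changes of adenoma over non-adenoma liver (x axis) for the 10 genes with the largest increase and 9 of the 10 with the largest decrease past the threshold, where points are estimates from limma and bars are SE. Values run from -8.00 for Dct to 7.22 for Afp.

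Of 19 tested oncofetal and tumour marker genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 3.58. The list passed camera (adjusted p = 6.26e-09) but not with an estimated correlation (adjusted p = 0.477 with an estimated correlation). Cd63, a tetraspanin of late endosomes, rose by 3.72 ± 0.55 (adjusted p = 1.44e-06), and the imprinted gene Ndn fell by 0.59. Of 24 cell cycle genes, 23 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.98 (camera adjusted p = 1.88e-09, and adjusted p = 0.834 with an estimated correlation). The kinase gene Cdk1, well above background on 2 of 10 non-adenoma arrays, rose by 3.61 ± 0.55, the cyclin gene Ccna2 by 2.95 ± 0.48 and the kinesin gene Kif20a by 2.67 ± 0.41, each higher in 10 of 10 adenomas. Bub1, a mitotic checkpoint kinase, fell by 0.44. Within slide run 1, with 4 arrays in each group, the list medians were 5.16 for oncofetal and 2.47 for cell cycle genes, and within run 2, with 5 in each, they were 3.08 and 1.93.

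Of 18 genes of gluconeogenesis, the urea cycle and amino acid metabolism, 16 fell and 0 rose by limma, with the same numbers adjusted over the list alone and a median of -1.64 (camera adjusted p = 0.000523, and adjusted p = 0.834 with an estimated correlation). Gnmt, which methylates glycine, fell by 2.20 ± 0.32 and the urea cycle gene Ass1 by 2.02 ± 0.31, both lower in 10 of 10 adenomas. Of 23 respiratory chain genes, 15 fell (15 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 0.00215, and adjusted p = 0.834 with an estimated correlation). Uqcrc1 of complex III fell by 1.65 ± 0.23 and the cytochrome c oxidase subunit gene Cox5a was 2.14-fold lower. Of 25 genes of fatty acid oxidation, 16 fell and 1, Cpt1a, rose (16 and 1 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 0.0396, and adjusted p = 0.834 with an estimated correlation). The carnitine palmitoyltransferase gene Cpt2 fell by 1.14 ± 0.24. Of 18 genes of bile acid synthesis and transport, 13 fell and 1, Abcc2, rose (14 and 1 adjusted over the list alone), with a median of -1.04 (camera adjusted p = 0.0281, and adjusted p = 0.834 with an estimated correlation). The bile acid importer gene Slc10a1 fell by 1.92 ± 0.41 and Baat, which conjugates bile acids, by 1.42 ± 0.25. Within runs 1 and 2 the medians were -1.70 and -1.39 for amino acid metabolism, -0.87 and -0.44 for the respiratory chain, -1.21 and -0.26 for fatty acid oxidation and -1.67 and -0.54 for bile acid genes.

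Of 12 periportal genes, 9 fell (9 adjusted over the list alone), with a median of -1.78 (camera adjusted p = 0.0283, and adjusted p = 0.834 with an estimated correlation), and the medians within runs 1 and 2 were -1.12 and -3.03. The ammonia-handling gene Etnppl fell by 3.96 ± 0.63. Adenomas 7 and 9 had periportal medians of -6.26 and -5.88 against the control mean, and the other 8 adenomas lay between -1.09 and -0.04. Of 17 pericentral genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of -0.68, and the list did not pass camera (adjusted p = 0.955). Its median was -3.87 within run 1 and 1.35 within run 2, so its direction differed between the runs. Cyp2e1, a pericentral P450, fell by 2.25 ± 0.66 (adjusted p = 0.00415) and Znrf3, which limits Wnt signalling, rose by 0.89 ± 0.27 (adjusted p = 0.00561), but did not pass with normexp (0.43) or array weights (0.40). Glul, the pericentral glutamine synthetase gene, had a value of -1.22 ± 0.73 and did not pass (adjusted p = 0.153), with 5 of 10 adenomas on each side of the non-adenoma mean. Within run 1 it was -4.74 and passed, and within run 2 it was 1.35 and did not. With array weights it was -1.32 and passed.

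Of 12 stellate cell genes, 9 fell (9 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 0.0137, and adjusted p = 0.834 with an estimated correlation), and the medians within runs 1 and 2 were -1.48 and -0.77. The receptor gene Ngfr fell by 2.35 ± 0.29 and the matrix protein gene Ecm1 by 2.38 ± 0.32. Of 13 macrophage genes, 7 fell (7 adjusted over the list alone), with a median of -1.11, and the list did not pass camera (adjusted p = 0.106) but passed the directional test of fry (adjusted p = 0.0201). The scavenger receptor gene Cd163 fell by 2.51 ± 0.44 and was well above background on 8 of 10 adenomas. Timd4, a receptor of resident macrophages, fell by 1.96 ± 0.36. Of 13 sinusoidal endothelial genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), and the receptor gene Eng fell by 1.14 ± 0.17 (camera adjusted p = 0.253, fry adjusted p = 0.00443). For macrophage and sinusoidal endothelial genes the share that changed was not above the 54.7% of all genes that passed. Of 12 hepatocyte genes, 2 rose and 4 fell (2 and 3 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.955).

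Of 24 p53 target and DNA damage genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.164) but passed the mixed test of fry (adjusted p = 0.000132). Over all genes 54.7% passed in this comparison, a larger share than in this list, and fry does not compare a list with other genes. Polk, a translesion polymerase gene, rose by 1.08 ± 0.18, Mdm2, which restrains p53, rose by 0.74 ± 0.14, and the proapoptotic Bbc3 was 2.15-fold lower. Cdkn1a, a cell cycle inhibitor, had a value of 0.54 ± 0.48 (adjusted p = 0.346) and the acute phase gene Saa1 -0.88 ± 0.68 (adjusted p = 0.274). The female-biased P450 gene Cyp2b9 had a value of -0.90 ± 0.44 (adjusted p = 0.0807). None of these 3 passed in the main fit, but Cdkn1a (0.54) passed with a block of replicate numbers and Cyp2b9 (-1.08) with array weights. Cyp7b1, an oxysterol hydroxylase, fell by 1.99 ± 0.58 (adjusted p = 0.00409, lower in 8 of 10), but did not pass with a block of replicate numbers. Of 35 lists, camera called 2 higher and 6 lower, fry called 21, and camera with an estimated correlation called 0 (lowest adjusted p = 0.477). Median, mean and camera direction differed in sign for 3 lists, 0 of which were called by camera.

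Slide run was a term of the fit, and 5919 genes passed within run 1 and 4054 within run 2. Each of these runs had a single scan date for these 2 groups. In run 1, however, all adenomas lay on slide 4 and all non-adenoma arrays on slide 3. In run 2 only slide 8 held both groups. The fits within runs therefore do not separate group from slide. Znrf3 (0.04) did not pass within run 1, and Bex2 (3.59), Krt20 (3.61), Cyp2e1 (-0.33) and Cyp7b1 (-0.57) did not pass within run 2. With normexp correction 4035 genes passed. Adenoma 10 correlated better with arrays of the groups without adenoma tissue (0.979) than with adenomas (0.931), and its oncofetal median was 0.46 where the other 9 adenomas lay between 1.76 and 5.48.

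**Figure D2:**
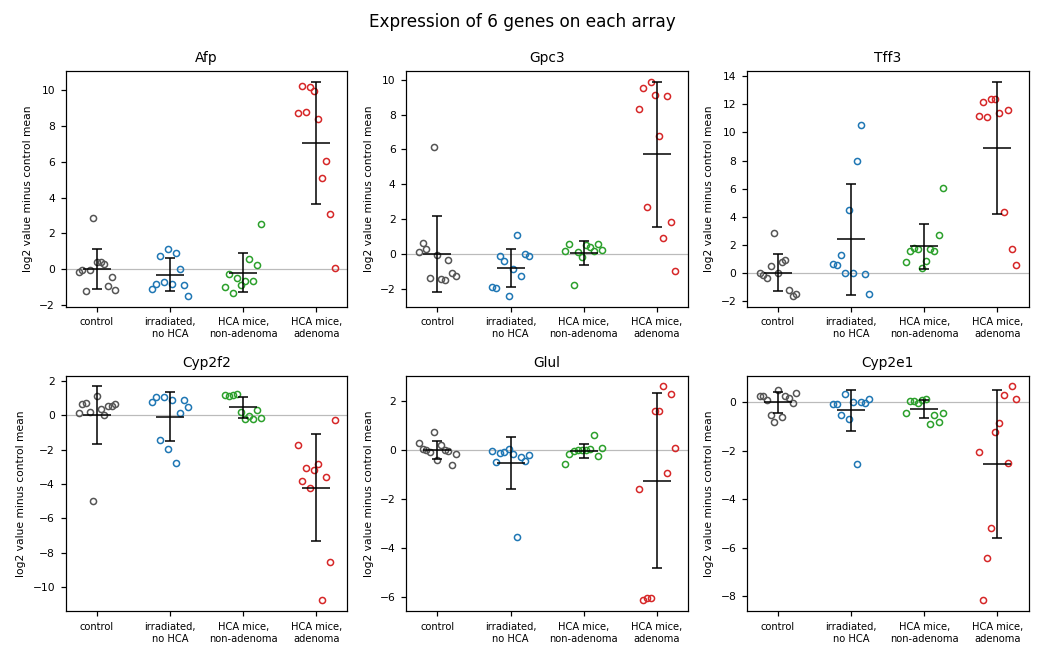
Expression of Afp, Gpc3, Tff3, Cyp2f2, Glul and Cyp2e1 on each array, as the log2 value minus the mean of the controls (y axis) in the 4 groups, with a point per array and black bars for mean ± SD. Afp in adenomas reached 10.19 above the control mean in adenoma 2 and was 0.10 in adenoma 10, and Glul lay between -6.14 and 2.60 in adenomas.

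Against irradiated liver without HCA, the comparison asked how adenomas differed from liver of irradiated mice in which no adenoma was present. Afp rose by 7.04 ± 0.82 (adjusted p = 2.09e-07, higher in 10 of 10), Akr1c18 by 6.70 ± 0.81 (adjusted p = 2.51e-07, 9 of 10) and Rbp7, a retinol-binding protein gene, by 4.74 ± 0.51 (adjusted p = 8.33e-08, 10 of 10). Cyp2f2 fell by 4.12 ± 0.78 (adjusted p = 7.13e-05, lower in 10 of 10), and Scnn1a, a subunit gene of the epithelial sodium channel, fell by 3.63 ± 0.52 (adjusted p = 2.01e-06, 10 of 10).

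In limma, 6029 genes (47.4%) passed, 2650 higher and 3379 lower, and the median over all genes was -0.06. Gpc3 rose by 6.21 ± 1.06, Tff3 by 6.23 ± 1.43, Tspan8 by 5.63 ± 0.79, Krt20 by 5.08 ± 0.92, Cela1 by 4.63 ± 0.56, Bex1 by 4.36 ± 0.73 and Prnd by 4.34 ± 0.49. In irradiated liver without HCA, Tff3 and Cela1 were well above background on 4 of 10 arrays, Gpc3 on 3, Krt20 on 2, and Bex1, Prnd and Rbp7 on 1. Tff3 was also high on irradiated 8 and 7, at 10.51 and 7.95 above the control mean. Dct fell by 6.38 ± 1.14, Lrtm1 by 4.54 ± 0.81, Sult2a7 by 4.51 ± 0.97, Cyp8b1 by 4.21 ± 0.67 and Srgap3, a regulator of the cytoskeleton, by 3.56 ± 0.69. In adenomas Cyp8b1 and Srgap3 were well above background on 4 of 10 arrays. A1bg fell by 4.83 ± 1.47 (adjusted p = 0.00723) and Hamp2 by 4.13 ± 1.16 (adjusted p = 0.004), and with slide as a random block their values were -4.07 and -3.28 and did not pass.

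Of 19 oncofetal genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 3.07 (camera adjusted p = 2.35e-08, and adjusted p = 0.526 with an estimated correlation). Of 24 cell cycle genes, 19 rose (20 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 7.56e-06, and adjusted p = 0.88 with an estimated correlation). Cdk1, well above background on 5 of 10 irradiated arrays, rose by 2.76 ± 0.56 (0.58 and not past the threshold with normexp) and Kif20a by 2.24 ± 0.42. Of 21 cholesterol synthesis genes, 7 rose (6 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.0286, and adjusted p = 0.88 with an estimated correlation), and fry did not call the list (adjusted p = 0.155). Cyp51, a demethylase of the pathway, rose by 1.42 ± 0.31. Within run 1 (4 adenomas, 2 irradiated) and run 2 (5 and 5) the medians were 5.14 and 2.87 for oncofetal, 2.27 and 0.88 for cell cycle and 0.44 and 0.88 for cholesterol genes.

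Of 12 stellate cell genes, 10 fell (10 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 0.000172, and adjusted p = 0.88 with an estimated correlation), and Ngfr fell by 2.32 ± 0.30 and the transcription factor gene Lhx2 by 2.17 ± 0.29. Of 13 macrophage genes, 10 fell (10 adjusted over the list alone), with a median of -1.35 (camera adjusted p = 0.00519, and adjusted p = 0.88 with an estimated correlation). Cd163 fell by 3.23 ± 0.45, and Csf1r, the receptor for a macrophage growth factor, by 1.76 ± 0.36. Macrophage medians were 3.44 on irradiated 7, 2.02 on irradiated 3 and 1.99 on irradiated 5 against the control mean. Of 12 periportal genes, 8 fell (9 adjusted over the list alone), with a median of -1.69 (camera adjusted p = 0.0128, and adjusted p = 0.88 with an estimated correlation), and Etnppl fell by 3.25 ± 0.64. Of 18 genes of amino acid metabolism, 14 fell (15 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 0.0021, and adjusted p = 0.88 with an estimated correlation), and the urea cycle gene Asl fell by 1.64 ± 0.28 and Gnmt by 1.80 ± 0.33. Of 19 glycolysis genes, 10 fell (11 lower and 1 higher adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.0178, and adjusted p = 0.88 with an estimated correlation). Hk3, a hexokinase gene of leukocytes, fell by 1.76 ± 0.36 and the isomerase gene Gpi1 by 0.85 ± 0.18, of which Gpi1 did not pass with normexp (-0.43). Of 23 respiratory chain genes, 12 fell (12 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.0286, and adjusted p = 0.88 with an estimated correlation), and Uqcrc1 fell by 1.31 ± 0.23. Within runs 1 and 2 the medians were -1.67 and -1.23 for stellate, -1.46 and -1.95 for macrophage, -0.92 and -2.62 for periportal, -1.64 and -0.90 for amino acid, -0.72 and -0.77 for glycolysis and -0.76 and -0.37 for respiratory chain genes. On the scan date with 5 adenomas and irradiated 6 and 7 they were 2.42 for oncofetal, 0.83 for cell cycle, 1.22 for cholesterol, -1.56 for stellate, -2.02 for macrophage, -2.18 for periportal, -0.52 for amino acid, -0.39 for glycolysis and -0.09 for respiratory chain genes.

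Cdkn1a (-0.54 ± 0.49, adjusted p = 0.366), Glul (-0.45 ± 0.75, adjusted p = 0.635), Saa1 (-0.47 ± 0.69, adjusted p = 0.593) and Cyp2b9 (-0.76 ± 0.45, adjusted p = 0.162) did not pass. With array weights Cyp2b9 (-1.33) passed. Cyp7b1 fell by 1.40 ± 0.59 (adjusted p = 0.0479) and did not pass with normexp (-0.88), quantile scaling (-1.34), no filter (-1.40) or slide as a random block (-1.28). Of 35 lists, camera called 3 higher and 6 lower, fry called 16, and camera with an estimated correlation called 0 (lowest adjusted p = 0.526). Median, mean and camera direction differed in sign for 3 lists, 0 of which were called by camera.

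Within run 1 4565 genes passed and within run 2 1060, but in run 1 the 2 groups were scanned on different dates. With scan date as a term 1219 genes passed, with slide as a random block 3419 and with only the 2 groups in the fit 3794. On scan date 5, which held 5 adenomas and irradiated 6 and 7, limma called 0 genes, with 1782 at an unadjusted p under 0.05. The only other scan date with both groups, 3, held adenoma 10 and irradiated 8, 9 and 10. The fits by scan date thus lean on few arrays. Among these are irradiated 7 and 8, which stood apart, and adenoma 10, which resembled non-adenoma liver. Of 33 named genes that had passed, 15 did not with scan date as a term, among them Tff3 (4.67), Dct (-4.09), Cdk1 (1.90) and Uqcrc1 (-0.86). Cyp7b1 had a value of 0.47 within scan date 5, so its direction turned.

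**Figure D3:**
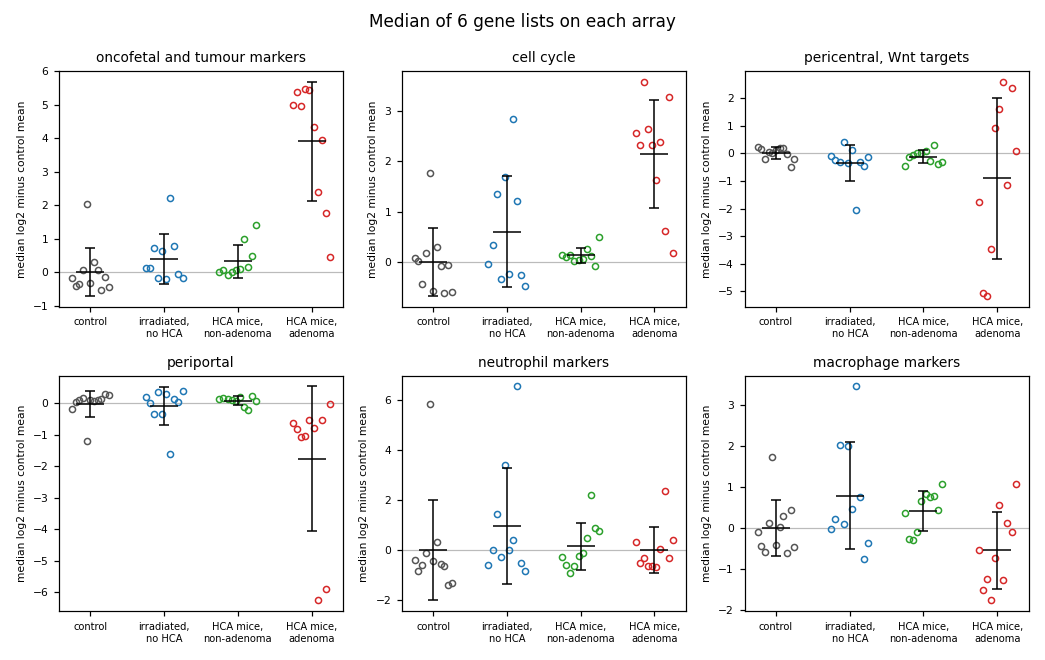
Median over the genes of 6 fixed lists on each array, as log2 minus the mean of the controls (y axis) in the 4 groups, with a point per array and black bars for mean ± SD. The oncofetal median lay between 0.46 and 5.48 in adenomas, and the neutrophil median was 6.52 on irradiated 8 and 5.84 on control 5.

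Irradiated liver without HCA was compared with control liver to ask what long irradiation at a low dose rate left in liver of mice without HCA. No gene passed: the largest of the values given here was 2.03 ± 0.53 for Slc4a1, the anion exchanger of red cells (adjusted p = 0.407, higher on 9 of 10 irradiated arrays). Rsad2, an interferon-induced antiviral gene, had a value of 1.16 ± 0.30 (adjusted p = 0.407, 8 of 10), and Cry1, a clock repressor, -0.87 ± 0.25 (adjusted p = 0.453, lower on 9 of 10). Lists of chemokines, cell cycle genes and macrophage genes passed camera as higher, and those of fatty acid oxidation and the respiratory chain as lower, but none of these calls held with an estimated correlation or by fry.

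In limma 0 of 12716 genes passed (lowest adjusted p = 0.391), 1151 had an unadjusted p under 0.05, and the median over all genes was -0.05. This unadjusted number was 1995 without control 5, 764 without control 6, 572 without irradiated 7, 445 with normexp and 533 within scan date 4, with 0 genes called by limma in each. With array weights 118 genes passed, 12 higher and 106 lower, and within run 1 (2 irradiated and 3 control arrays) 19 passed, with 1848 and 2246 unadjusted. In run 1 the irradiated arrays lay on slide 2 and the controls on slide 1. The fit within run 1 does not separate group from slide. Limma called 0 genes within run 2 (5 and 5 arrays, 573 unadjusted), within run 3 (3 and 3, 454 unadjusted) and with slide as a random block (697 unadjusted). Camera called 14 lists higher and 2 lower, fry called 0 (lowest adjusted p = 0.173) and camera with an estimated correlation called 0 (lowest adjusted p = 0.196). Median, mean and camera direction differed in sign for 8 lists, 0 of which were called by camera.

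Of 23 cytokine and chemokine genes, 22 had positive values, with a median of 0.63 (camera adjusted p = 9.04e-11, and adjusted p = 0.196 with an estimated correlation). Vcam1, a leukocyte adhesion receptor, had a value of 1.11 ± 0.36, and Ccl2, a monocyte chemokine, of 1.00 ± 0.35 (adjusted p = 0.547 for both). Of 24 cell cycle genes, 22 had positive values, with a median of 0.56 (camera adjusted p = 2.99e-09, and adjusted p = 0.319 with an estimated correlation). The replication gene Mcm3 had a value of 0.45 ± 0.20 (adjusted p = 0.547). Of 13 macrophage genes, 13 had positive values, with a median of 0.69 (camera adjusted p = 9.48e-08, and adjusted p = 0.319 with an estimated correlation), among them the complement gene C1qb at 0.88 ± 0.33 and the lipid receptor gene Trem2, well above background on 10 of 11 controls, at 1.53 ± 0.59. Of 5 erythroid genes, 4 passed adjusted over the list alone, all higher, against 0 over all genes by limma, with a median of 0.91 (camera adjusted p = 8.04e-06, and adjusted p = 0.196 with an estimated correlation). Of 23 interferon genes 21 had positive values, and 1, Rsad2, passed adjusted over the list alone (camera adjusted p = 3.27e-06, and adjusted p = 0.319 with an estimated correlation). All 7 neutrophil genes had positive values, with a median of 0.68 (camera adjusted p = 0.00451, and adjusted p = 0.517 with an estimated correlation). For S100a8, a calcium-binding protein of neutrophils, 5 of 10 arrays were higher (1.28 ± 0.78, adjusted p = 0.597). In no list other than those of erythroid, interferon, clock and T cell genes did a member pass adjusted over the list alone, and Cry1 and the T cell coreceptor gene Cd4 (-0.46 ± 0.12, adjusted p = 0.407, well above background on 8 of 10 irradiated arrays) passed there as lower.

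The highest values of these genes lay on a few arrays. The erythroid median was also 0.93, 0.58 and 0.56 on irradiated 1, 2 and 4, which did not stand apart. It was 0.17, -0.02 and -0.54 on irradiated 9, 6 and 10, and -0.39 on control 5. Slc4a1 was 5.93, 5.68, 3.61 and 2.99 above the control mean on irradiated 3, 5, 8 and 7, the macrophage median was 3.44 on irradiated 7, and the neutrophil median was 6.52 on irradiated 8 and 3.37 on irradiated 5, but also 5.84 on control 5. Within runs 1, 2 and 3 the list medians were 0.42, 0.81 and 0.46 for chemokines, 0.22, 0.64 and 0.58 for cell cycle, 0.51, 1.20 and 0.15 for macrophage, 0.98, 1.38 and 0.20 for erythroid, 0.16, 0.37 and 0.28 for interferon and 0.34, 0.24 and 2.54 for neutrophil genes. Without control 5 and irradiated 5, 7 and 8, a choice made after seeing the data, camera called 15 lists and limma 0 genes (500 at an unadjusted p under 0.05). Without irradiated 3 as well, camera called 7 lists and limma 0 genes (323 unadjusted).

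Of 24 p53 target and DNA damage genes, 17 had positive values, with a median of 0.16 (camera adjusted p = 0.00312, and adjusted p = 0.196 with an estimated correlation). Phlda3, a p53 target that restrains Akt, had a value of 0.70 ± 0.35 (adjusted p = 0.55, and 1.17 and past the threshold within run 1), the proapoptotic Bax 0.28 ± 0.13 and the stress gene Sesn1 0.32 ± 0.15 (adjusted p = 0.547 for both), and Cdkn1a 0.66 ± 0.47 (adjusted p = 0.652). In run 1 the 2 groups lay on separate slides, so the call of Phlda3 there cannot be told from a slide difference. Within runs 1, 2 and 3 the list median was 0.21, 0.12 and 0.09. On scan date 4, with 3 irradiated and 5 control arrays, it was 0.02. Irradiated 7 was the highest of the irradiated arrays for the list (0.46 against the control mean) and for Phlda3 (2.54), and irradiated 5 for Cdkn1a (4.26). Of 25 genes of fatty acid oxidation, 2 had positive values, with a median of -0.30 (camera adjusted p = 0.00339, and adjusted p = 0.846 with an estimated correlation), and the peroxisomal gene Ehhadh had a value of -0.56 ± 0.32 (adjusted p = 0.576). Within runs 1, 2 and 3 the median of this list was 0.31, -0.51 and -0.42, so its direction differed in run 1, where Ehhadh was 0.22. Of 23 respiratory chain genes 0 had positive values in limma, with a median of -0.18 (camera adjusted p = 0.0131, and adjusted p = 0.915 with an estimated correlation) and medians of 0.13, -0.25 and -0.28 within the runs. Values that did not pass were -0.25 ± 0.79 for Afp, -0.65 ± 0.71 for Glul, 0.81 ± 0.66 for Saa1, -0.26 ± 0.57 for Cyp7b1 and -0.26 ± 0.43 for Cyp2b9.

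Non-adenoma liver of mice with HCA was compared with irradiated liver of mice without HCA, to ask how liver that carries an adenoma elsewhere differed. No gene passed. Bcl6, a transcriptional repressor, had a value of -0.95 ± 0.32, Cdkn1a of -1.08 ± 0.49 and Gadd45b, a stress gene, of -1.36 ± 0.58 (adjusted p = 0.729 for each), and Bcl6 and Gadd45b were lower on 10 of 10 non-adenoma arrays than the irradiated mean. Lists of cell cycle, chemokine and matrix genes passed camera as lower, and those of the respiratory chain and fatty acid oxidation as higher, but none of these calls held with an estimated correlation or by fry.

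In limma 0 of 12716 genes passed (lowest adjusted p = 0.729), 621 had an unadjusted p under 0.05, and the median over all genes was 0.06. This unadjusted number was 988, 1167, 300, 1123 and 286 without irradiated 1, 4, 5, 6 and 7. It was 2617 with normexp, 2800 with scan date as a term, 382 with only the 2 groups and 1044 with array weights, and limma called 0 genes in each of these fits. Within run 2 (5 and 5 arrays) 30 genes passed, all higher, while limma called 0 within run 1 (4 and 2, 460 unadjusted), on the scan date with 5 non-adenoma arrays and irradiated 6 and 7 (1272 unadjusted) and with slide as a random block (614 unadjusted). Camera called 5 lists higher and 9 lower, fry called 0 (lowest adjusted p = 0.721) and camera with an estimated correlation called 0 (lowest adjusted p = 0.762). Median, mean and camera direction differed in sign for 7 lists, 0 of which were called by camera.

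Of 24 cell cycle genes, 2 had positive values, with a median of -0.51 (camera adjusted p = 1.11e-08, and adjusted p = 0.762 with an estimated correlation). Mcm3 had a value of -0.49 ± 0.20. The median of 23 chemokine genes was -0.35 (camera adjusted p = 2.33e-05, and adjusted p = 0.762 with an estimated correlation), and Tnfaip3, an inhibitor of NF-kB, had a value of -0.73 ± 0.35. The median of 20 matrix genes was -0.38 (camera adjusted p = 6.75e-05, and adjusted p = 0.762 with an estimated correlation), and the collagen gene Col4a1 had a value of -0.61 ± 0.29. The median of 13 macrophage genes was -0.29 (camera adjusted p = 0.00903, and adjusted p = 0.762 with an estimated correlation), and Marco, a scavenger receptor, had a value of -1.58 ± 0.90. All 23 respiratory chain genes had positive values, with a median of 0.22 (camera adjusted p = 0.0016, and adjusted p = 0.762 with an estimated correlation). The median of 25 genes of fatty acid oxidation was 0.29 (camera adjusted p = 0.00565, and adjusted p = 0.762 with an estimated correlation). Ppara, the nuclear receptor of this pathway, had a value of 0.54 ± 0.25 and Cpt2 of 0.48 ± 0.24, and the glycolysis gene Aldoa had a value of -0.53 ± 0.21 and Slc4a1 of -1.19 ± 0.56, all with an adjusted p of 0.729. In each of the 35 lists 0 members passed adjusted over the list alone in limma.

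The irradiated arrays that stood apart are in this comparison too, on the other side. Within runs 1 and 2 the medians were -0.02 and -0.87 for cell cycle, -0.21 and -0.66 for chemokine, -0.13 and -0.40 for matrix, -0.07 and -0.92 for macrophage, 0.06 and 0.11 for respiratory chain and 0.05 and 0.18 for fatty acid oxidation genes, but in run 1 the 2 groups were scanned on different dates. On the scan date with 5 non-adenoma arrays and irradiated 6 and 7 they were -1.22, -0.85, -0.94, -1.22, 0.36 and 0.81 in the same order. Without control 5 and irradiated 5, 7 and 8, a choice made after seeing the data, camera called 6 lists and limma 0 genes (151 unadjusted), and Tnfaip3 was 0.02. Without irradiated 3 as well, camera called 13 lists and limma 0 genes (406 unadjusted), and Tnfaip3, Marco and Slc4a1 were 0.08, 0.61 and 0.44, so their direction turned. Afp (-0.18 ± 0.82), Glul (0.77 ± 0.75), Saa1 (0.41 ± 0.69), Cyp7b1 (0.58 ± 0.59) and Cyp2b9 (0.14 ± 0.45) did not pass.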

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

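The tests of splits of the samples were planned before their results were seen, and the tests on arrays that stood apart, on adenoma 10 and on adenomas 7 and 9 were chosen after. Dixon's ratio, the gap of the highest or lowest array to its neighbour divided by the range of its group, was computed for 35 lists and 81 genes in the 3 groups of 10 arrays, and 56 of 348 values lay beyond its critical value. Chance puts about 1 in 20 groups beyond it, and genes and lists on an array are not independent.

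Irradiated 7 gave 33 of these values. It was lowest for Glul (0.847), Asl (0.731), Cyp8b1 (0.71), Dct (0.67), Cyp2e1 (0.649), Scnn1a (0.583), Gnmt (0.561), Lrtm1 (0.553), Sult2a7 (0.522), Cyp51 (0.515), Ppara (0.509) and Ass1 (0.471). It was also lowest for the lists of the clock (0.711), hepatocytes (0.688), complement and coagulation (0.66), pericentral (0.651), periportal (0.631), amino acid metabolism (0.625), P450 (0.596), cholesterol synthesis (0.593), bile acids (0.564), male-biased (0.559) and female-biased genes (0.547). It was highest for Prnd (0.722), Elovl7 (0.716), Ccl2 (0.649), Phlda3 (0.573), Cd63 (0.555), Tspan8 (0.555), Kif20a (0.521) and Bex1 (0.518), and for the lists of oncofetal (0.592) and p53 genes (0.544). Irradiated 5 was highest for Gadd45b (0.579), Cdkn1a (0.523) and ER stress genes (0.49). Irradiated 8 was highest for Saa1 (0.504) and lowest for Hamp (0.511), and irradiated 3 was highest for interferon genes (0.474).

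Among non-adenoma arrays, 8 was lowest for Cyp2b9 (0.813) and Alas2 (0.513) and highest for T cell genes (0.545), and 3 was lowest for Gpc3 (0.674) and sinusoidal endothelial genes (0.5) and highest for Nr1d1 (0.501). Array 4 was lowest for Bax (0.663), 7 was lowest for Dct (0.487) and 9 was highest for Cela1 (0.507). Non-adenoma 10 was highest for Tff3 (0.59) and Afp (0.498). Among adenomas, 8 was highest for neutrophil genes (0.641), and 10 was lowest for Elovl7 (0.667), Rbp7 (0.51) and Prnd (0.467) and highest for amino acid metabolism (0.546) and Uqcrc1 (0.52).

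Control 5 and irradiated 5, 7 and 8 stood apart from the other arrays without adenoma tissue, and all 4 had a leukocyte list above every other control and irradiated array. For control 5 and irradiated 7 and 8, the test of a slide or scan batch could not decide. Of 9 other arrays without adenoma tissue on their slides, 0 had a median correlation below 0.966, the lowest on slides that held none of the 4. The lowest of these 9 was 0.977, although all were at 0.96 or above by choice, which left the test little room. It shows only that the low correlations were not shared by whole slides. For irradiated 5 a batch cannot be told apart, since on its slide 1 of 3 others lay below 0.966. This was irradiated 3 at 0.961, with macrophage and T cell medians of 2.02 and 1.82. That 0 of 12 in all lay under the limit of 0.96, set after the correlations were seen, follows from the choice of arrays and tests nothing. A lower share of hepatocytes alone is argued against in 4 of 4, since the lists of other cell types moved apart by at least 3.30, against at most 2.55 elsewhere. The hepatocyte median was -1.4 on irradiated 7, and -0.13, 0.13 and -0.24 on control 5, irradiated 5 and irradiated 8. Whether a lower share added to the pattern on irradiated 7 was not tested. More leukocytes in the piece of liver may account for part of the pattern, with 4 of 4 arrays showing it. Irradiated 7 also correlated slightly better with adenomas (0.876) than with arrays without adenoma tissue (0.866), and whether it held adenoma tissue was not tested. Infection, tumours elsewhere or the irradiation itself stay untested.

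Adenoma 10 resembled non-adenoma liver. A swap with an ordinary adenoma among the non-adenoma arrays is argued against, since 0 of them correlated better with adenomas. In a further test run after that result, their slopes on the fold changes of adenomas 1 to 9 were -0.208 to 0.163. Arrays of the other groups were not covered by these tests, and irradiated 7 did correlate better with adenomas (0.876 against 0.866). Adenoma 10 had a slope of 0.086 on the fold changes of the other adenomas, which themselves had slopes of 0.751 to 1.362, so little adenoma tissue in the section or a single wrong label may account for it. Non-adenoma 10 had Tff3 at 6.04 above the control mean and an oncofetal median of 1.41, the highest of its group, against 0.54 and 0.46 in adenoma 10. No biological explanation was tested.

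Adenomas 7 and 9 had high pericentral medians (2.60 and 2.40) and low periportal medians (-6.26 and -5.88). Residual non-adenoma liver may add to the difference from other adenomas, since over genes outside both lists 2 of 2 slopes on the fold changes of adenomas 1 to 6 and 8, 0.734 and 0.558, lay below theirs (0.749 to 1.221), the first narrowly, but another kind of adenoma would lower a slope too, and a mix with such liver alone leaves pericentral medians above 0.30, the highest in non-adenoma liver, unaccounted for. For the low periportal genes the test of a slide batch could not decide. Of the 2 other adenomas on the slide, 6 and 8 at -0.81 and -0.52, 0 lay below every array without adenoma tissue (lowest -1.61). Adenomas 7 and 9 were picked as the low ones after seeing the data, so this outcome followed from the choice. It shows only that the low values were not shared by the whole slide. For the high pericentral genes a slide batch cannot be told apart. Of the 2 other adenomas, 1 lay above every array without adenoma tissue, adenoma 6 at 1.63, and adenoma 8 at -1.16 did not. No biological explanation was tested.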

How the results depend on the processing

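Fits within scan dates, list tests within runs and with scan date as a term, fits of named genes by run, by scan date and of only the 2 groups, and fits without arrays that stood apart were chosen after seeing the data, and the other alternatives were planned. The direction of the excess of lower over higher genes in both adenoma comparisons held under every alternative that called any gene. The cause of each change below was not tested, except where an alternative has fewer arrays or a stricter threshold by construction. Leaving out each array in turn gave 0 to 0 genes in limma for irradiated liver without HCA against control (572 to 1995 unadjusted) and 0 to 0 for non-adenoma liver against it (286 to 1167 unadjusted), 6421 to 7392 for adenoma against non-adenoma liver and 5415 to 6676 for adenoma against irradiated liver without HCA. Signal over background limits Cdk1, Bex2 and Cela1, which were well above background on few non-adenoma arrays.

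For irradiated liver without HCA against control, where limma called 0 genes (1151 unadjusted), array weights gave 118, and run 1, the same arrays as scan date 1, gave 19. In that run the 2 groups lay on separate slides. List calls changed from 16 to 7 with array weights, 0 with an estimated correlation, 0 by fry, 15 without the 4 arrays apart, and 7 without those and irradiated 3. For non-adenoma liver against irradiated liver without HCA, run 2 gave 30 genes, and list calls changed from 14 to 8 with array weights, 0 with an estimated correlation, 0 by fry, 6 without the 4 arrays, and 13 without those and irradiated 3. For adenoma against non-adenoma liver, 6957 genes became 4035 with normexp, 1889 with a log2 fold change of at least 1, and 4054 within run 2, the same arrays as scan date 5. List calls changed from 8 to 0 with an estimated correlation, 21 by fry, and 19 within run 1, the same arrays as scan date 2. For adenoma against irradiated liver without HCA, 6029 genes became 3419 with slide as a random block, 1219 with scan date as a term, 3794 with only the 2 groups, 1452 with a log2 fold change of at least 1, 1060 within run 2 and 0 within scan date 5 (1782 unadjusted). List calls changed from 9 to 14 with array weights, 0 with an estimated correlation, 16 by fry, 18 within run 1, 15 without the 4 arrays, and 15 without those and irradiated 3.

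Named genes were refitted under normexp, quantile and median scaling, the deposited table, no filter, no run term, slide as a random block, the replicate block and array weights as planned, and under scan date, only the 2 groups, within runs and dates, and without arrays that stood apart as added. They were not refitted with the stricter filter, by single probes, at other thresholds or leaving out each array. In these fits the direction turned for 1 gene that had passed, Cyp7b1 in adenoma against irradiated liver without HCA within scan date 5 (0.47). The other values that turned had not passed. In irradiated liver without HCA against control these were Afp with normexp (0.07) and with slide as a random block (0.01), Cyp2b9 with array weights (0.06), Ehhadh within run 1 (0.22), Saa1 and Cyp2b9 within run 2 (-0.16 and 0.04), and Nr1d1, Afp and Cyp7b1 within run 3, the same arrays as scan date 3 (-0.08, 0.05 and 0.22). Cyp7b1 and Cyp2b9 turned within scan date 4 (0.35 and 0.48), Cyp2b9 without the 4 arrays apart (0.12), and Ehhadh and Cyp2b9 without those and irradiated 3 (0.03 and 0.14). In non-adenoma liver against irradiated liver without HCA, Afp turned without the run term (0.12), with slide as a random block (0.02), with array weights (0.32) and with only the 2 groups (0.32), and Tnfaip3 (0.04) and Cyp2b9 (-0.25) with array weights. Afp, Saa1 and Cyp2b9 turned within run 1 (0.20, -0.12 and -0.02) and Cyp2b9 within run 2 (-0.23). Tnfaip3, Afp and Cyp2b9 turned without the 4 arrays (0.02, 0.28 and -0.43), and without those and irradiated 3 (0.08, 0.52 and -0.45), where Marco (0.61) and Slc4a1 (0.44) did too. In adenoma against non-adenoma liver Glul turned within run 2 (1.35). In adenoma against irradiated liver without HCA, Cdkn1a turned with array weights (0.16) and within scan date 5 (0.11), and Glul and Saa1 with scan date as a term (1.01 and 0.04), within run 2 (2.19 and 0.10) and within scan date 5 (3.27 and 0.71). Saa1 also turned without the 4 arrays (0.06) and without those and irradiated 3 (0.05).

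Counted once per gene and planned setting, named genes lost their call 4 and 27 times, for 3 and 19 genes. They gained it 3 times and 1 time. These numbers are for adenoma against non-adenoma and against irradiated liver, in this order. The 3 gains were Cdkn1a (0.54) with the replicate block, and Glul (-1.32) and Cyp2b9 (-1.08) with array weights. The 1 gain was Cyp2b9 (-1.33) with array weights. In the added fits, of 42 named genes that had passed between adenoma and non-adenoma liver, 1 did not within run 1 and 4 did not within run 2. Of 33 that had passed between adenoma and irradiated liver, 2 did not with only the 2 groups, 15 with scan date as a term, 5 within run 1, 14 within run 2, and none of the 33 passed in limma within scan date 5. Glul and Cyp2b9 gained a call within run 1 in both adenoma comparisons, and Cyp2b9 also without the 4 arrays, and without those and irradiated 3. In irradiated liver without HCA against control, Cd4 (-0.41) gained its call with array weights and Phlda3 (1.17) within run 1, where group and slide coincided.

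With the replicate number as a block, adenoma against irradiated liver without HCA gave 487 genes, and adenoma against non-adenoma liver gave 14 list calls. The block also turned Cyp2b9 (0.01) in irradiated liver without HCA against control, Afp (0.43) in non-adenoma liver against irradiated liver without HCA, and Glul (0.42) and Saa1 (0.52) in adenoma against irradiated liver without HCA. Of the 4 and 27 lost calls, 2 and 19 came with the block. The 2 were Cyp2e1 (-2.25) and Cyp7b1 (-1.99). In adenoma against irradiated liver without HCA, Gpc3 and Tff3 lost theirs and both had values of 6.65 (6.21 and 6.23 without the block). Samples share only a number: of 10 same-numbered pairs in each comparison, 4, 4, 3 and 2 had deviations correlated above 0.1, and 2, 3, 3 and 1 samples correlated best with their own number, in the order above.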

Other observations

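The split tests were planned before their results were seen, and the values per adenoma were looked at after. Of 17 female-biased genes, 8 fell and 1 rose between adenoma and non-adenoma liver (8 and 1 adjusted over the list alone), with Ntrk2 falling by 3.13 and the sulfotransferase gene Sult1e1 by 2.46, and of 15 male-biased genes 9 fell (11 lower and 1 higher adjusted over the list alone), with the elongase gene Elovl3 falling by 3.68. Camera called neither (adjusted p = 0.127 and 0.116), and the directional test of fry called both (adjusted p = 0.00324 and 0.00181). Of 15 genes of the growth hormone and insulin axis, 5 fell and 2 rose, with the same numbers adjusted over the list alone. Igfals, which carries IGF1 in plasma, fell by 2.53, Igf1 fell by 1.27 and Igfbp1 rose by 2.50. Of 13 senescence genes 4 rose and 3 fell, with the same numbers adjusted over the list alone, and the cell cycle inhibitor gene Cdkn2b rose by 3.03. Over all genes 54.7% passed in this comparison. The share that changed was not above this in the female-biased, growth hormone and senescence lists, so these counts are not particular to them.

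Markers of 3 cell types had under 5 tested genes and no list test. Of exocrine pancreas, Cela1 rose by 4.81 in adenoma against non-adenoma liver, Ctrb1 fell by 0.54 and Cel fell by 0.66, and Cela3b had a value of 0.03 and did not pass. Of dendritic cells, Xcr1 fell by 0.49 and Batf3 fell by 1.41, and Itgax (1.08) and Zbtb46 (0.23) did not pass. Of adipocytes, Lipe fell by 0.34 and Car3 fell by 2.69, and Cidec (0.58) did not pass.

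Pericentral genes differed between single adenomas. Against the control mean, Glul was -1.57, -6.14, -6.02, -6.03, 1.61, 1.60, 2.60, -0.95, 2.30 and 0.07 in adenomas 1 to 10, and Axin2, a target of Wnt signalling, was -3.49, -6.08, -5.81, -5.81, 0.91, 1.92, 2.41, -1.62, 2.46 and -0.34. Adenomas 1 to 4 shared slide 4 and held the 4 lowest pericentral medians, -1.76, -5.05, -5.18 and -3.47. The 10 non-adenoma arrays, 4 of them scanned on the same date, had pericentral medians between -0.44 and 0.30, the lowest of them on that date.

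Among 100 splits of the 2 groups compared, the real one included, the real one gave the most genes in both adenoma comparisons. For adenoma against non-adenoma liver 1 of 100 gave as many as 6957 genes (highest other 5585). For adenoma against irradiated liver without HCA 1 of 100 gave as many as 6029 (highest other 2893). This argues against chance only for splits of single arrays, and 1 of 100 is the lowest share possible. The splits drew arrays across slides and runs. Most slides held 1 group and the correlation within slide was 0.22, so the splits do not separate group from slide. Chance cannot be excluded for the gene counts of 0 in limma, which 100 of 100 splits reach by construction. The highest other counts there were 1530 for irradiated liver without HCA against control and 1 for non-adenoma against irradiated liver without HCA. A split that called 1530 genes where the real one called 0 points to a structure of the samples. For no list count can chance be excluded. As many lists as the real 16 came from 43 of 100 splits of irradiated and control liver (highest other 24), as many as 14 from 34 of non-adenoma and irradiated liver (highest other 20), as many as 8 from 64 of adenoma and non-adenoma liver (highest other 20), and as many as 9 from 87 of adenoma and irradiated liver (highest other 24).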
